A study of Zea mays subsp. mays with 6 samples.

How the data were processed

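Messenger RNA of maize anthers was sequenced in 6 libraries, 1 for each of 3 genotypes at each of 2 anther lengths, 0.4 mm and 0.7 mm. The genotypes were fertile wild type of the inbred line W23, the mutant mac1 introgressed into W23, and the mutant ocl4 in the inbred line A188. Total RNA was extracted with either of 2 reagents, and which reagent served which library was not stated. Libraries were made with an mRNA kit and read on an Illumina HiSeq instrument. The deposited values were raw counts: the authors collapsed identical reads of a library into 1 sequence tag and gave the number of times it was read, with no scaling. The tags were 18 to 48 nt long. The authors named Bowtie and TopHat as their aligners, and the role and version of both were not given in the sources used here. The files held no positions, gene names or annotation, and no genome was used here, so the tags were not assigned to genes. Values of the genes mac1, ocl4 and msca1, and lists of genes named by an annotation, were therefore not analysed here.

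The comparisons, the 4-fold size rule for single sequences, the miRNA target motifs, the named-item rule and the alternatives for scaling, filter, pseudocount, repeated tags, mismatches and tags with several matches were chosen before the data were examined. Reads that hold a miRNA target motif were counted as planned. Because tags could not be assigned to genes, substitutes for gene values were made afterwards: reads that encode a peptide signature of a protein family, and contigs assembled from the tags. CPM stands for counts scaled to 1000000 reads of a library, and for contigs to 1000000 reads placed on 1 contig.

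A read was taken to hold the target motif of miR2118 or miR2275 if any stretch of it, on either strand, matched the 22-nt complement of the miRNA with up to 3 mismatches. Read from the other strand, this motif is the miRNA sequence, so transcripts of the miRNA genes count as well. The same search with 20 shuffled versions of each motif gave the background. Each level has a 95% exact Clopper-Pearson interval, and each ratio of 2 libraries has the exact conditional binomial interval.

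Protein families were counted from peptide signatures: conserved patterns, or windows of 9 residues with at least 6 distinct residues from a conserved protein. The signatures and the miRNA sequences were written from general knowledge of these families and not taken from a database, so a family name rests on the signature alone. A read counted once for a family if its translation in any of 6 frames held a signature. There were 102 families in 17 lists, and reversed signatures served as decoys. Some patterns were shortened or extended after a search of 1 library, before any libraries were compared. Decoys took 5 to 32 reads per library, against 490789 to 706394 reads for the signatures. Ratios were formed for families with at least 20 reads in 1 of the libraries compared. A family was said to have risen or fallen, or to be higher or lower, if the libraries differed at least 2-fold and the 95% interval of the ratio excluded 1. This rule was set after values had been seen. For lists with at least 3 such families, the median log2 ratio was placed as a percentile among the medians of 10000 random lists of families of like mean level. These lists were dictated by which proteins have short conserved stretches and stand in for the planned gene lists.

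The rule for named items took, in wild type, the 10 families with the highest and the 10 with the lowest log2 ratio of CPM plus 1. For each mutant against wild type, it took the 10 highest and 10 lowest among families that differed the same way at both lengths, ranked by the smaller of the ratios. It also allowed up to 4 members of each list with the largest ratio, and not all of these are named in the text. Its minimum of 10 CPM was lowered to 1 CPM, after levels were seen, because a signature covers a small part of a transcript. Other families named in the text were chosen after their values were seen. Results of measured families that are not named in the text are not reported here.

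Contigs were assembled from the wild-type and mac1 libraries with a k-mer extender written for these data (k of 31, k-mers seen at least 4 times, extension where the best next base had at least 4 times the count of the others). There were 107671 contigs of at least 100 nt, with a median of 157 nt, and 9876 reached 500 nt. Contigs are not genes, and 1 transcript can give several. Tags of at least 31 nt were placed end to end with up to 2 mismatches by bwa 0.7.19-r1273 (minimum seed 15, minimum score 21, clipping penalty 100), and tags with equally good places were left out. Between 64.4% and 69.9% of such reads had 1 place. In each library 0.0170% to 0.137% had several. The 96801 contigs with at least 1 CPM in any library were compared by log2 ratios with a pseudocount of 1 CPM, and a contig counted as higher or lower at 4-fold. On counts simulated with 200 planted changes, the rule recovered 82.0% to 89.5% of 6-fold and 91.0% to 94.0% of 8-fold changes, and called 0 of the unchanged contigs. Changes were planted only in contigs well above the 1 CPM minimum. Contigs near that minimum cannot reach 4-fold with this pseudocount, so recovery does not extend to them. The simulated counts carried counting error only, so the 0 calls do not cover differences in preparation between libraries.

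With 1 library per group, no test against replicate spread could be made, and no p-value is given. Intervals and the limit allowed by a count of 0 (3 counts) cover counting error only, since reads are not independent molecules. A difference is thus between 2 libraries, and its cause can lie in the genotype, the plants or the preparation. In ocl4 against wild type the mutation and the inbred line cannot be separated. In mac1 against wild type the mutation cannot be separated from donor segments that may remain after introgression.

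The sum over motif contigs without the contig most read in mac1 was also added after the data had been seen. Alternatives were edgeR 4.0.16 TMM scaling, a pseudocount of 0.1 CPM for contigs and 1 CPM for families, no filter, a filter of 5 CPM, distinct tags counted once, exact matches, shared tags, and motif searches with up to 2 or 4 mismatches or scaled to reads on 1 contig. Contigs of at least 500 nt, centring on GC content in 10 bins and the C-terminal part of signature proteins were added after the data had been seen. Coverage along transcripts was measured on 19 signature proteins of at least 70 residues with at least 50 window reads in each library, as the share of window reads in the N-terminal of 2 equal parts of the stretch used. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, matplotlib 3.10.9, g++ 11.4.0 and R 4.3.3 were used. A search anchored on poly(A) tails was dropped because too few reads held them.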

Results

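The study sequenced messenger RNA from maize anthers of 0.4 mm and 0.7 mm in 3 genotypes: fertile wild type, mac1 and ocl4. The gene mac1 encodes a small secreted protein, and its loss gives too many archesporial cells at the cost of the somatic layers of the anther lobe. The gene ocl4 encodes a class IV homeodomain leucine zipper (HD-ZIP IV) protein of the epidermis. Wild type was the inbred line W23, mac1 had been introgressed into W23, and ocl4 was in the inbred line A188. There was 1 library for each of the 6 groups, so no value has a replicate error and all intervals cover counting error only. Wild type gave 24348635 reads at 0.4 mm and 26258784 at 0.7 mm. The mac1 libraries held 30614360 and 26511543 reads, and the ocl4 libraries 25295233 and 27276196. A count of 0 allowed a level of up to 0.0980 to 0.123 CPM, depending on the library. Reads were not assigned to genes. The values are those of reads with miRNA target motifs, of reads that encode signatures of protein families, and of contigs assembled from the wild-type and mac1 reads.

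The libraries differed in how reads were spread along transcripts. Over 19 signature proteins, the median share of reads in the N-terminal part of the stretch was 38.8% and 39.9% in wild type at 0.4 mm and 0.7 mm. It was 50.6% and 46.2% in mac1, and 50.2% and 49.6% in ocl4. In every comparison of a mutant with wild type, the ratio was higher in the N-terminal than in the C-terminal part for 19 of 19 proteins. The median difference in log2 ratio was 0.82 for mac1 and 0.68 for ocl4 at 0.4 mm, and 0.37 and 0.52 at 0.7 mm. Contigs of the highest GC content, at least 67.4%, had median log2 ratios of 0.38 to 0.59 in these comparisons, against -0.17 to -0.06 for contigs of at most 39.5% GC. Reads of 5.8S ribosomal RNA ranged from 15.7 CPM in wild type at 0.7 mm to 1393 CPM in ocl4 at 0.7 mm.

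**Figure D1:**
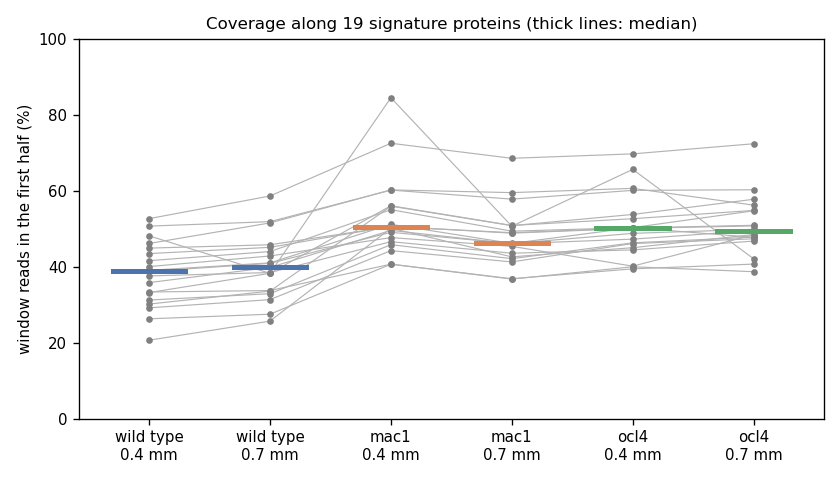
Share of signature reads (vertical axis, in percent) that fell in the N-terminal part of 19 signature proteins in each of the 6 libraries (horizontal axis); each grey line is 1 protein and each thick coloured line the median of a library. The medians of wild type, 38.8% and 39.9%, lie under those of both mutants, 46.2% to 50.6%.

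The series concerns phased small interfering RNAs (phasiRNAs), whose long noncoding precursors are cut at sites for miR2118 or miR2275. Since both strands were searched, reads and contigs with a motif can also come from transcripts that hold the miRNA itself. Reads with a miR2118 target motif stood at 10.2 CPM (95% interval 8.996 to 11.6) in wild type at 0.4 mm and 5.90 CPM (5.01 to 6.91) at 0.7 mm. In mac1 they stood at 4.15 CPM (3.46 to 4.94) and 6.79 CPM (5.83 to 7.86). In ocl4 they stood at 0.395 CPM (0.190 to 0.727) and 0.403 CPM (0.201 to 0.722), which is 10 and 11 reads. Shuffled motifs averaged 0.0377 to 0.118 CPM, and 1 of the 20 reached the ocl4 counts while 0 of 20 reached those of wild type or mac1. The level in ocl4 was 25.9-fold lower than in wild type at 0.4 mm (log2 ratio -4.69, 95% interval -5.77 to -3.79) and 14.6-fold lower at 0.7 mm (-3.87, -4.90 to -2.99). With up to 4 mismatches it was 10.1-fold and 7.67-fold lower. Between the lengths, wild type went down (log2 ratio -0.79, -1.09 to -0.50) and mac1 up (0.71, 0.38 to 1.05), both by less than 2-fold. With up to 2 mismatches the rise in mac1 was slight, from 2.16 to 2.45 CPM (66 and 65 reads). In ocl4 no change was detectable at this depth (0.03, -1.35 to 1.42). At 0.4 mm mac1 was 2.47-fold lower than wild type (-1.30, -1.62 to -0.99). At 0.7 mm the interval of mac1 against wild type included 0 (0.20, -0.12 to 0.52).

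Contigs with the motif also had far fewer reads in ocl4. The 16 contigs with a miR2118 motif together took 127 and 83.0 CPM in wild type, 71.0 and 109 CPM in mac1, and 2.52 and 2.44 CPM in ocl4. In mac1, 353 and 486 of the reads came from 1 contig that had 2 and 2 reads in wild type. Over all 16, mac1 at 0.7 mm was 1.32-fold of wild type (log2 ratio 0.40, 0.30 to 0.49), with 8 contigs higher and 8 lower. Without the 1 contig mac1 took 53.95 and 82.8 CPM and wild type 127 and 82.9 CPM. That contig was left out for being the most read in mac1, so mac1 could only go down. The excess of the mac1 sum at 0.7 mm thus depends on this contig. The sum over all 16 was 50.6-fold lower in ocl4 at 0.4 mm and 34.0-fold lower at 0.7 mm, with 14 of the 16 lower at each length. From 0.4 mm to 0.7 mm, 15 of 15 contigs with a ratio other than 0 went down in wild type, while 13 went up and 2 down in mac1. The contigs came from the wild-type and mac1 libraries, in the W23 background and without ocl4 reads. A lower sum in ocl4 was thus favoured by construction. Of reads placed on contigs, 77.6% and 78.1% matched exactly in ocl4, against 90.6% to 90.95% in wild type and mac1. The most read tag with the motif, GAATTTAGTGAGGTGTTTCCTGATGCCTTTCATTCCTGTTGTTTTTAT, was seen 8 and 2 times in wild type, 2 and 4 times in mac1, and 0 times in ocl4.

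Motif reads for miR2275 were rarer. They stood at 2.01 CPM (1.49 to 2.66) and 1.26 CPM (0.865 to 1.76) in wild type and at 0.523 CPM (0.299 to 0.849) and 1.02 CPM (0.671 to 1.48) in mac1. In ocl4 the levels of 0.198 and 0.257 CPM were near the 0.243 and 0.1998 CPM that shuffled motifs averaged there. At 0.4 mm the mac1 level was 3.85-fold lower than in wild type (log2 ratio -1.95, -2.86 to -1.11). Shuffled motifs averaged 0.278 CPM in that mac1 library, and 2 of 20 reached its count. The 2 contigs with this motif took 167 and 134 reads in wild type and 21 and 93 in mac1. In ocl4 they took 0 reads at both lengths. With up to 4 mismatches the motif levels of wild type were 0.913 and 1.06 times those of ocl4, and at 0.4 mm mac1 (16.01 CPM) lay above wild type (13.1 CPM). These differences in motif reads thus hold only for the stricter searches. The looser search took 363 reads in ocl4 at 0.4 mm, against 5 with up to 3 mismatches. No background was taken off it, so it cannot decide on the differences.

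**Figure D2:**
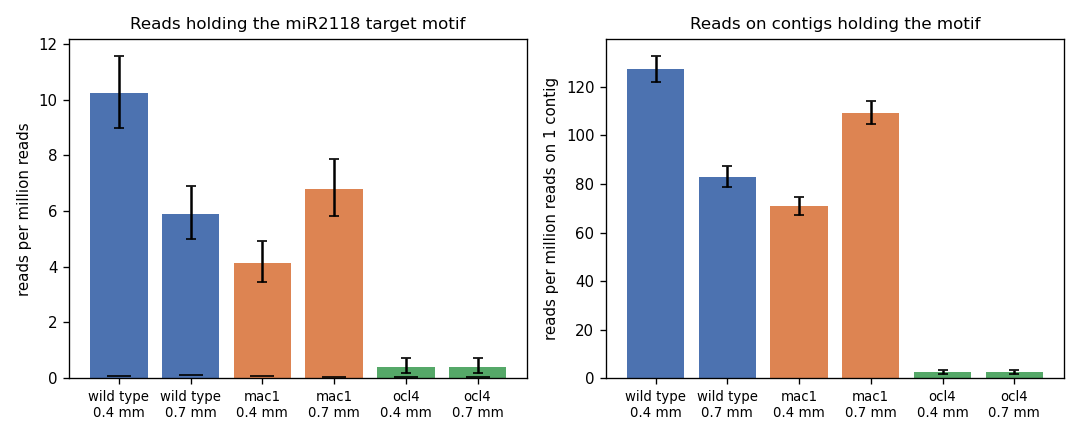
Reads with the miR2118 target motif (left, in CPM of all reads) and reads on the 16 contigs that hold it (right, in CPM of reads on 1 contig) in the 6 libraries; bars are levels, error bars 95% counting intervals and black dashes at left the mean of 20 shuffled motifs. Both ocl4 libraries lie at 0.403 CPM or less at left and at 2.52 CPM or less at right.

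Wild type at 0.7 mm against 0.4 mm asked what changed in normal anthers between these lengths. Of 68 protein families, 5 rose and 0 fell. DMC1, the recombinase specific to meiosis, rose 2.05-fold (95% interval 1.81 to 2.33) from 14.4 to 29.5 CPM. The light-harvesting chlorophyll a/b proteins rose 2.01-fold and the small subunit of Rubisco, the enzyme that fixes carbon dioxide, 3.27-fold. PEP carboxylase rose 2.28-fold and phenylalanine ammonia-lyase, the entry enzyme of phenylpropanoid synthesis, 2.16-fold, from 11 and 12 reads to 27 and 28. The 2-fold mark was missed by DMC1 (log2 ratio 0.95) and the light-harvesting family (0.92) with TMM scaling. With each distinct tag counted once it was missed by DMC1 (0.67), the light-harvesting family (0.77), PEP carboxylase (0.78) and phenylalanine ammonia-lyase (0.75). With a pseudocount of 1 CPM, 1 of the 5 families stayed 2-fold higher, the Rubisco small subunit (1.27). Over C-terminal parts, measured for 3 of the 5, 2 stayed 2-fold higher and the light-harvesting family had 0.96.

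All 3 photosynthesis families with enough reads for a ratio rose, and their median log2 ratio, 1.19, was at the 99.8th percentile of random lists. The other members had too few reads: photosystem II D1 went from 14 to 5 reads and the Rubisco large subunit had 3 and 3. The list of DNA replication and cell division had a median of -0.20, at percentile 1.24, with 0 of 9 families past the rule; histone H4 had -0.42, histone H2B -0.41 and PCNA, the sliding clamp of DNA polymerase, -0.39. In the meiosis and recombination list the median was -0.12. Other list medians were 0.04 for the cytoskeleton, -0.02 for translation, 0.26 for housekeeping, -0.03 for the small RNA pathway and 0.04 for transcription factors. For anther lobe signalling the median was 0.29, for cell wall and lipids -0.02, for membrane and proteolysis -0.02 and for stress 0.04. These lay between percentiles 16.6 and 93.5. Other families named by the rule lay above 0: HSP90 (0.60), cytosolic GAPDH (0.49), protein disulfide isomerase (0.53), S-adenosylmethionine synthetase (0.64) and GSK3-type kinase (0.48). Below 0 lay xyloglucan endotransglucosylase (-0.75), SMC ATPase (-0.68), class I small heat shock protein (-0.64), NAC factors (-0.60), ribonucleotide reductase (-0.48), histone H2A.Z (-0.39) and alpha-expansin (-0.36). The intervals of SMC ATPase, the small heat shock protein, NAC factors and ribonucleotide reductase included 0. Of 96801 contigs, 17 were 4-fold higher and 123 were 4-fold lower at 0.7 mm, 0.145% in all. A pseudocount of 0.1 CPM gave 1067 contigs.

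In mac1 more families and contigs were past the size rules for the same step. Of 80 families, 12 rose and 5 fell, and 568 contigs were 4-fold higher and 752 were 4-fold lower. Of these families 10 and 3 stayed 2-fold apart with distinct tags counted once, and 8 and 3 with a pseudocount of 1 CPM. Photosynthesis led: the light-harvesting proteins rose 11.8-fold (log2 ratio 3.56, 3.41 to 3.71) from 13.7 to 162 CPM and the Rubisco small subunit 17.6-fold. The Rubisco large subunit rose 7.51-fold and the photosystem II protein D1, both encoded in the plastid, 60.3-fold, each from 4 reads. How much of such plastid transcripts the mRNA kit took up was not measured for any library. PEP carboxylase, the fifth member, had a log2 ratio of -0.13. The list median was 3.56, at the 99.8th percentile. Of 12 cell wall and lipid families, 5 rose and 0 fell, with a median of 0.58 at percentile 98.6. In this list 8 families lay above 0 and 4 below. The latter were cellulose synthase (-0.77), 3-ketoacyl-CoA synthase (-0.57), class III peroxidase (-0.48) and alpha-expansin (-0.01). Phenylalanine ammonia-lyase rose 9.19-fold. The chalcone synthase type, which makes flavonoid precursors, went from 0 to 160 reads (at least 49.5-fold higher by the 95% interval). Acyl-CoA synthetases of the 4CL or ACOS type rose from 1 to 43 reads (49.7-fold, 95% interval 8.45 to 2006). DMC1 rose 3.28-fold (2.86 to 3.78), from 9.02 to 29.6 CPM. Profilin, HD-ZIP I factors, lipoxygenase and cytochrome P450 made up the rest, at 2.12-fold to 3.34-fold.

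Families that fell in mac1 were the MCM helicase of DNA replication (2.41-fold lower), kinesins (2.89-fold), MutS homologs of mismatch repair (2.71-fold), HD-ZIP IV factors (2.81-fold) and the largest subunit of RNA polymerase II (6.64-fold). The DNA replication list had a median of -0.34 at percentile 4.01, the small RNA pathway -0.72 at percentile 3.50 and meiosis and recombination -0.64 at percentile 4.72. Argonautes of the AGO1 and AGO10 type, which bind miRNAs, went from 341 to 207 CPM (-0.72). N-terminal parts had lower ratios than C-terminal parts for 19 of 19 proteins here, by a median of -0.22. For the same step in wild type they had higher ratios for 18 of 19 proteins, by a median of 0.13. None of the families that fell in mac1 had a C-terminal part to measure, so the part played by coverage in their fall is not known. Each of them was also higher in mac1 than in wild type at 0.4 mm. Their fall and that excess share the mac1 library of 0.4 mm and are not independent results. With a filter of 5 CPM, which leaves fewer families, the DNA replication median was 0.03. Over C-terminal parts, measured for 3 of its 11 families, it was 0.37, but the same 3 had a median of 0.23 over all windows. With distinct tags counted once the small RNA median was 0.00. The split of the 4-fold contigs turned with TMM scaling, from 43.0% to 57.6% higher, as the median contig moved from -0.11 to 0.02; a pseudocount of 0.1 CPM gave 5821 contigs.

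In ocl4 few families changed between the lengths. Of 77 families, phenylalanine ammonia-lyase rose 3.80-fold, from 10 to 41 reads, and HD-ZIP III factors, which pattern organ polarity, fell 2.003-fold, from 39 to 21 reads. With a pseudocount of 1 CPM both families missed the 2-fold mark, the first with a log2 ratio of 0.84. The HD-ZIP III factors also missed it with TMM scaling (log2 ratio -0.97) and with distinct tags counted once (-0.60). DMC1 went from 18.3 to 29.4 CPM (0.68, 0.51 to 0.85) and AGO1 and AGO10 argonautes from 333 to 220 CPM (-0.60). The small RNA list had a median of -0.60 at percentile 0.270, and photosynthesis 0.24 at percentile 96.2 with 5 of 5 families above 0. There were 96 contigs 4-fold higher and 51 lower at 0.7 mm, and 813 in all with a pseudocount of 0.1 CPM. The size of the length step was not tested for a difference between genotypes.

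**Figure D3:**
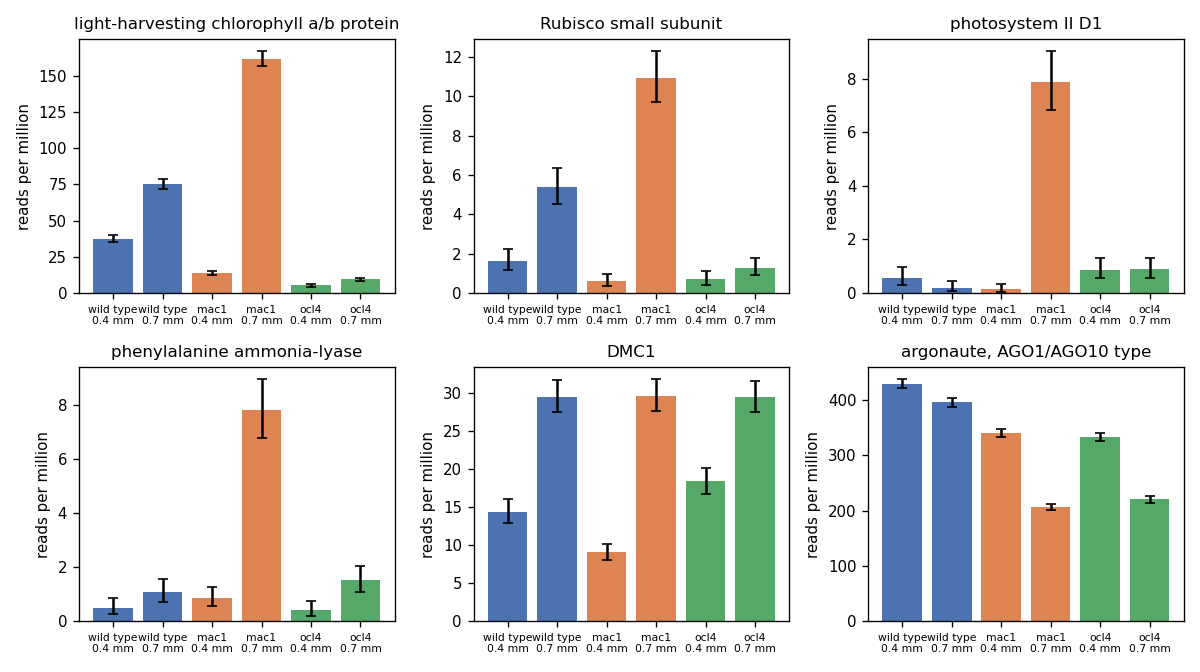
Levels (CPM, vertical axes) of 6 protein families in the 6 libraries, as bars with 95% counting intervals. Light-harvesting reads lie between 5.30 CPM (ocl4, 0.4 mm) and 162 CPM (mac1, 0.7 mm), and DMC1 reads lie at 29.4 to 29.6 CPM in all 3 genotypes at 0.7 mm.

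The comparison of mac1 with wild type asked which transcripts differ when the lobe has excess archesporial cells. Both mutants were compared with the same wild-type libraries, so a trait of those libraries would appear in both comparisons. Since mac1 was introgressed into W23, donor segments that may remain cannot be told apart from the mutation. At 0.4 mm 24 of 76 families were higher and 4 lower, and at 0.7 mm 22 of 76 were higher and 1 lower. These counts stand on a general shift: the median over all families was 0.48 and 0.37. Over the 19 proteins used for coverage, the median was 0.22 and 0.40 in the N-terminal part but -0.46 and -0.17 in the C-terminal part, so the direction of the shift turned with the part measured. Higher at both lengths were sucrose synthase (3.56-fold and 3.47-fold), S-adenosylmethionine synthetase (3.02 and 3.42), ERF (3.16 and 2.90) and NAC (3.93 and 3.602) transcription factors, 14-3-3 proteins (2.75 and 2.48) and polyubiquitin (2.04 and 2.42). HD-ZIP IV factors were 6.17-fold and 2.17-fold higher, and HD-ZIP III factors 2.68-fold and 9.66-fold higher, the last from 4 reads in wild type. MADS box factors, many of which set floral organ identity, were 2.17-fold higher at 0.7 mm and had a log2 ratio of 0.84 at 0.4 mm. Among the remaining families named by the rule, calcium-dependent protein kinases were 2.64-fold higher at 0.4 mm and had 0.81 at 0.7 mm, and Aux/IAA proteins had 0.92 and 0.95. Coverage differed too, with a higher ratio in the N-terminal part for 19 of 19 proteins at both lengths.

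At 0.4 mm the lower families were histone H2B (2.21-fold), profilin (2.21-fold), the light-harvesting proteins (2.73-fold) and the Rubisco small subunit (2.65-fold). The photosynthesis list had a median of -1.40 at percentile 0.145, although PEP carboxylase was 3.11-fold higher. Members of the DNA replication and cell division list were split: the MCM helicase (2.83-fold), CDKB (3.36-fold), cyclins (2.78-fold) and kinesins (3.18-fold) were higher, while histone H4 (-0.82) and histone H3.1 (-0.39) lay below 0 beside histone H2B. The list median, 0.26, was at percentile 33.4. Members of this list with a C-terminal part to measure lay below 0 over it: histone H4 (-1.06), PCNA (-0.46) and CDKA (-0.11). The higher members had no such part, so how far coverage makes the split is not known. HSP90 was 3.82-fold higher (3.67 to 3.98), and cellulose synthase 2.96-fold. The housekeeping list had a median of 1.26 at percentile 98.7, and meiosis and recombination -0.56 at percentile 1.61, although the MutS homologs in that list were 2.34-fold higher (1.30 to 4.41). The largest ratio of mac1 to wild type at 0.4 mm was that of the largest subunit of RNA polymerase II, 54.9-fold higher (9.53 to 2199) with 69 reads against 1. At 0.7 mm photosystem II D1 was 41.4-fold higher and the chalcone synthase type 22.6-fold. Phenylalanine ammonia-lyase was 7.32-fold higher, lipoxygenase 4.95-fold, xyloglucan endotransglucosylase 3.80-fold and the light-harvesting proteins 2.15-fold. TCP factors were 4.04-fold lower there, with 5 against 20 reads. In the cell wall and lipid list 12 of 12 families were above 0 at 0.7 mm and 7 were past the rule (median 1.23, percentile 95.3). At 0.7 mm the meiosis and recombination list had a median of -0.65 at percentile 0.51, with 1 of 3 families above 0. Housekeeping had 0.81 at percentile 96.8 and the small RNA pathway -0.40 at percentile 4.72. DMC1 was level at 0.7 mm (0.01, -0.14 to 0.15, and -0.17 over its C-terminal part), and AGO1 and AGO10 argonautes had -0.34 and -0.94 at the 2 lengths. Other families low at both lengths were SMC ATPase, HSP101, enolase and 4 ribosomal proteins (L23, S14, S15 and S23), none past the rule.

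Contigs 4-fold apart between mac1 and wild type numbered 4968 higher and 1629 lower at 0.4 mm, and 1947 higher and 1381 lower at 0.7 mm. At 0.4 mm TMM scaling moved the median contig from 0.16 to -0.02 and the share of higher contigs from 75.3% to 65.3%. A pseudocount of 0.1 CPM gave 21185 and 10613 contigs. Of the 24 and 22 families higher at 0.4 mm and 0.7 mm, 20 and 22 stayed 2-fold higher with TMM scaling. With each distinct tag counted once 11 and 13 did, and 23 and 22 stayed above 0. With a pseudocount of 1 CPM 13 and 15 stayed 2-fold higher. Of the 4 and 1 lower families, 4 and 1 stayed 2-fold lower with TMM scaling, 2 and 1 with distinct tags, and 3 and 0 with the pseudocount. A C-terminal part could be measured for 1 and 3 of the higher families, and over it 0 and 1 stayed 2-fold higher, so for most of them the part played by coverage is not known.

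The comparison of ocl4 with wild type is between mutants in A188 and fertile W23, so its differences are those of mutation and inbred line together. At 0.4 mm 18 of 74 families were higher and 3 lower, and at 0.7 mm 20 of 77 were higher and 2 lower. The median over all families was 0.56 and 0.36. Over the 19 proteins it was 0.58 and 0.37 in the N-terminal part but -0.17 and -0.23 in the C-terminal part, so this shift too turned with the part measured. The light-harvesting proteins were 7.07-fold lower at 0.4 mm (log2 ratio -2.82, -3.09 to -2.56) and 7.99-fold lower at 0.7 mm (-2.999, -3.19 to -2.81). The Rubisco small subunit was 2.31-fold and 4.18-fold lower, and profilin 2.59-fold lower at 0.4 mm with -0.99 at 0.7 mm. In contrast, the plastid transcripts of photosystem II D1 and the Rubisco large subunit, whose uptake by the mRNA kit was not measured, were higher at 0.7 mm. They were 4.62-fold and 6.74-fold higher, from 5 and 3 reads. The photosynthesis list thus had medians of -1.21 (percentile 0.145) and -0.29 (percentile 2.90). The first turned to 0.60 with no filter on low counts, which lets families with few reads enter, and the second to 0.12 with distinct tags counted once.

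Some cell division families were higher in ocl4: CDKB 5.99-fold and 3.40-fold, the MCM helicase 2.34-fold and 2.22-fold, and kinesins 3.95-fold and 2.19-fold at 0.4 mm and 0.7 mm. The list as a whole did not stand out, with medians of 0.56 and 0.25 at percentiles 56.7 and 52.5, and histone H4 (-0.37) and histone H3.1 (-0.26) lay below 0 at 0.4 mm. The housekeeping list had medians of 1.10 and 0.88 at percentiles 98.8 and 97.4. At 0.7 mm the stress list had 1.19 at percentile 96.0, and meiosis and recombination -0.18 at percentile 4.86. The HD-ZIP IV class, to which the ocl4 product belongs, was 3.88-fold and 2.38-fold higher. ERF factors (2.74 and 2.06), 14-3-3 proteins (3.04 and 2.54), HSP90 (2.97 and 2.28), xyloglucan endotransglucosylase (2.34 and 4.08) and 3-ketoacyl-CoA synthase of very-long-chain fatty acid synthesis (2.65 and 4.15) were higher at both lengths. HD-ZIP IV factors, ERF factors and 14-3-3 proteins were higher at both lengths in mac1 too. In CPM, 14-3-3 proteins had 6.74 and 7.27 in wild type, 18.5 and 18.1 in mac1, and 20.5 and 18.5 in ocl4. Differences shared by both mutants cannot be told apart from a trait of the wild-type libraries. The largest subunit of RNA polymerase II was 34.7-fold higher at 0.4 mm, with 36 reads against 1, and 2.89-fold higher at 0.7 mm. DEAD-box helicases were 2.14-fold higher at 0.4 mm and had 0.88 at 0.7 mm, and beta-tubulin had 0.98 and 0.84. Among families below wild type at both lengths, none past the rule, were AGO1 and AGO10 argonautes (-0.37 and -0.85), AGO5 or MEL1 argonautes (-0.19 and -0.40), histone H2B (-0.67 and -0.29), HSP101, SMC ATPase and ribosomal protein L23. DMC1 had 0.35 at 0.4 mm and was level at 0.7 mm (0.998-fold, 0.903 to 1.10), but over the C-terminal part of the protein it had -0.05 and -0.33. Here too the ratio was higher in the N-terminal part for 19 of 19 proteins at both lengths.

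Contigs 4-fold apart between ocl4 and wild type numbered 2098 higher and 2771 lower at 0.4 mm, and 1229 higher and 2472 lower at 0.7 mm. The contigs were assembled without ocl4 reads, of which 64.4% and 64.7% were placed, against 69.9% and 69.4% in wild type, so the split leans to lower by construction. At 0.4 mm TMM scaling moved the median contig from 0.10 to -0.03 and the share of higher contigs from 43.1% to 31.7%. A pseudocount of 0.1 CPM gave 18182 and 13786 contigs, and the split at 0.4 mm turned, to 51.3% higher. Of the 18 and 20 families higher at 0.4 mm and 0.7 mm, 16 and 19 stayed 2-fold higher with TMM scaling and 8 and 12 with each distinct tag counted once. With a pseudocount of 1 CPM 11 and 6 did. The 3 and 2 lower families stayed 2-fold lower under the first 2 settings, and 2 and 2 did with the pseudocount. None of the higher families had a C-terminal part to measure, while the light-harvesting proteins and the Rubisco small subunit stayed 2-fold lower over theirs at both lengths.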

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

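Of the tests here, the assembly of ocl4 reads alone and the scaling and coverage tests of the photosynthesis families were set before their results were seen; all others were chosen after.

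Between 0.4 mm and 0.7 mm, 4 values moved in opposite directions in wild type and mac1 with log2 ratios past 0.5 either way and intervals that excluded 0. Smaller opposite moves, such as those of histone H4 (-0.42 and 0.29) and histone H2B (-0.41 and 0.28), fell under that limit. None of these differences was tested against replicate spread. Coverage also moved in opposite directions between the lengths. The median N-terminal minus C-terminal difference in log2 ratio was 0.13 in wild type and -0.22 in mac1. Reads with the miR2118 target motif had log2 ratios of -0.79 in wild type and 0.71 in mac1, a difference of -1.50. With up to 2 mismatches the rise in mac1 was slight, from 2.16 to 2.45 CPM (66 and 65 reads), while wild type went from 4.23 to 2.40 CPM. With up to 4 mismatches mac1 went from 12.5 to 24.3 CPM and wild type from 33.6 to 22.8 CPM. Reads with the miR2275 motif had -0.68 and 0.96, a difference of -1.64, but rest on few reads: the 16 and 27 reads of mac1 stood over shuffled means of 8.5 and 6.3, with 2 and 1 of 20 shuffled motifs at or above them. With up to 4 mismatches both directions turned, from 13.1 to 14.1 CPM in wild type and from 16.01 to 13.9 CPM in mac1. Every library then lay between 13.1 and 16.01 CPM with no background taken off, so that search cannot decide on the directions. Xyloglucan endotransglucosylase had -0.75 and 0.60, a difference of -1.34. HSP90 had 0.60 and -0.68, a difference of 1.28.

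Reads with the miR2118 target motif were 25.9-fold lower in ocl4 than in wild type at 0.4 mm. A looser search catches only some base differences between A188 and W23 inside the sites. With up to 4 mismatches wild type was 10.1 times ocl4, and 29.5 times with the mean of the shuffled motifs taken off. That mean can be uneven: with up to 3 mismatches 1 shuffled motif had 23 reads in ocl4, against a mean of 1.55. From 3 to 4 mismatches ocl4 went from 0.395 to 3.32 CPM and wild type from 10.2 to 33.6 CPM. Sites with more differences, or absent from A188, would still be missed, so this cause stays open. Motif reads were counted without contigs, so the choice of W23-background reads for the assembly bears only on the contig sums; there an assembly of ocl4 alone held 0 motif contigs against 11 of wild type, but the 21 motif reads of ocl4 would give 0.572 at the wild-type rate, so it cannot decide. Poorer 5′ coverage in ocl4 is argued against by the coverage difference of 0.68, which is in favour of the N-terminal part in ocl4. The inbred line and the mutation cannot be told apart: 10 of the 16 motif contigs had a read in ocl4 at 0.4 mm, and no A188 library without the mutation was analysed here. An effect of ocl4 on transcripts with the motif is the biological explanation that stays open. Whether these are precursors or transcripts of the miRNA genes was not settled.

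At 0.4 mm, 6597 contigs differed 4-fold between mac1 and wild type. With TMM scaling 5939 did, and with log2 ratios centred by GC content 5951 did, which argues against either as the whole cause. Coverage of the 5′ parts of transcripts was lower in wild type, by a median difference of 0.82 in log2 ratio over 19 of 19 proteins, and may account for part of the contigs; how many was not measured. A difference in cell composition of the mac1 anther also stays open and was not tested. The same holds for donor segments that may remain after introgression. Extraction with different reagents is another open source of such a shift, since the reagent of each library is not stated.

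In mac1 the light-harvesting family rose with a log2 ratio of 3.56 between the lengths. With TMM scaling the ratio was 3.77, and over the C-terminal part of the protein it was 3.57, which argues against scaling and against changed coverage as its cause. Green tissue carried over into the 0.7 mm sample cannot be told apart from a change in the anther: PEP carboxylase, abundant in maize leaves, had -0.13, but its level in such tissue was not measured here. A change in the mutant anther itself was not tested and stays open.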

How the results depend on the processing

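The contigs of at least 500 nt, the centring on GC content, the C-terminal parts and the sum of motif contigs without the contig most read in mac1 were chosen after the data had been seen. With 1 library per group no library was left out, and depth limits families under 20 reads and the ocl4 motif counts. Values of mac1, ocl4 and msca1 under other settings were not run, nor were exact matching and shared tags for families, since reads were not placed on genes.

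For 4-fold contigs, 49 of 63 alternative counts stayed within 1.5 times. A pseudocount of 0.1 CPM, which lets contigs with few reads pass, gave 1067, 5821 and 813 contigs for length in wild type, mac1 and ocl4. It gave 21185 and 10613 for mac1 against wild type at 0.4 mm and 0.7 mm, and 18182 and 13786 for ocl4. Contigs of at least 500 nt are fewer by construction, 9876 against 96801, and gave, in the same order, 35, 308, 35, 1005, 456, 889 and 622. As a share of the contigs compared, each of these counts was higher than that over contigs of all lengths.

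Levels of the motifs depend on the search by construction, as stricter or looser matching takes fewer or more reads. For miR2118 (wild type, mac1 and ocl4, each at 0.4 mm and 0.7 mm), up to 4 mismatches gave 33.6, 22.8, 12.5, 24.3, 3.32 and 2.97 CPM. Up to 2 gave 4.23 and 2.40 in wild type and 2.16 and 2.45 in mac1. Distinct tags gave 14.9 and 9.14 in wild type, 5.92 and 9.90 in mac1 and 0.747 in ocl4 at 0.7 mm. Scaled to reads on 1 contig, levels were 14.6, 8.51, 6.12 and 9.81 in wild type and mac1. For miR2275, up to 4 mismatches gave 13.1, 14.1, 16.01, 13.9, 14.4 and 13.3. Wild type was then 0.913 and 1.06 times ocl4, so no difference was seen. No background was taken off these levels, so they cannot decide on the difference. Up to 2 gave 0.986 and 0.571 in wild type, 0.261 in mac1 at 0.4 mm and 0.0733 in ocl4 at 0.7 mm. Distinct tags gave 3.08 and 2.13 in wild type and 0.956 and 1.48 in mac1. Scaled to reads on 1 contig, wild type had 2.88 and 1.81. The other 13 of 48 stayed within the counting interval. Wild type over ocl4 for miR2118 ranged from 7.67 to 23.8 across these settings and both lengths.

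The counts for lists cover those outside percentiles 5 to 95, and the counts for families cover those past the 2-fold rule. Of 100 alternative list medians 76 stayed within 0.25 and 6 changed sign. Photosynthesis in ocl4 against wild type went to 0.60 at 0.4 mm with no filter, which lets families with few reads enter, and to 0.12 at 0.7 mm with distinct tags counted once. In mac1 between the lengths, DNA replication went to 0.03 with a filter of 5 CPM and to 0.37 over C-terminal parts, both over fewer families, and the small RNA pathway to 0.00 with distinct tags. The small RNA pathway in mac1 against wild type at 0.7 mm went to 0.06 with no filter. Of 367 alternative family ratios 262 stayed within the counting interval and 1 changed sign: catalase in mac1 against wild type at 0.4 mm went to -0.0456 with distinct tags. Of all 133 ratios that had a C-terminal value, past the rule or not, 22 had the opposite sign over it, 21 of them from above 0 to below 0. The causes of the other moves were not tested.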

Other observations

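All observations here were chosen after their values had been seen.

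Glutaredoxins of the CC type, the class to which the anther gene msca1 belongs, gave 5, 4 and 5 reads at 0.4 mm in wild type, mac1 and ocl4, and 0 reads in each at 0.7 mm. Over the 3 genotypes this is 14 reads (0.174 CPM, 95% interval 0.0954 to 0.293) against 0. The point value is 4.65 times the level allowed by a limit of 3 counts over the 3 libraries of 0.7 mm, and this ratio leaves out the counting error of the 14 reads. The family stood under the minimum of 20 reads for a ratio, and its members cannot be separated.

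Over all its windows the recombinase DMC1 stood at 0.7 mm at 29.5, 29.6 and 29.4 CPM in wild type, mac1 and ocl4, from 14.4, 9.02 and 18.3 CPM at 0.4 mm. Over the C-terminal part alone, mac1 and ocl4 at 0.7 mm were 0.888-fold and 0.794-fold of wild type, so the near equality depends on the coverage of the N-terminal part. Argonautes of the AGO5 or MEL1 type, expressed in germ cells of grasses, lay between 37.9 and 54.6 CPM in the 6 libraries, and those of the AGO4 type between 1.83 and 4.18 CPM. Signatures of copia reverse transcriptase had 0 to 2 reads per library and those of gypsy 5 to 22. An anther-specific polyketide synthase of pollen wall synthesis had 0 reads in all 6 libraries. Transcripts of mitochondrial cytochrome oxidase subunit 1 had 0 to 6 reads.

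Between the mutants, which do not share an inbred line, 2628 contigs differed 4-fold at 0.4 mm and 2931 at 0.7 mm, of which 80.8% and 77.7% were higher in mac1. The contigs were assembled without ocl4 reads, of which 64.4% and 64.7% were placed, against 67.9% and 69.3% in mac1, so the split favours mac1 by construction. Coverage of N-terminal against C-terminal parts differed less between them, by medians of 0.07 and -0.20 in log2 ratio.

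Each library carried 1 adapter index in 96.99% to 98.2% of the reads that ran into an adapter. Of reads placed on contigs, the 20 most read contigs took 3.04% to 5.76%.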
